A study of Homo sapiens with 4 samples.

How the data were processed

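RNA-seq was made from 2 libraries of MDA-MB-231 and 2 of MDA-MB-231Br human breast cancer cells. Per the labels' protocols, the cells grew in DMEM with 10% FBS and RNA was isolated with a mirVana kit. The submitters' processing notes name HISAT2, featureCounts, DESeq2 and the build GRCh37, with no versions. The library kit, the read length, the gene annotation, the strand setting and any filter on genes are not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart, and genes with near-identical copies, such as ribosomal protein, HLA, histone, metallothionein and CXCL genes, are uncertain.

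The deposited table holds a size-factor-normalized read signal per gene. Its name speaks of counts, but the values are not whole. Each column consists of whole multiples of a single step, so dividing by that step gave whole reads for 100% of values in all 4 libraries, within a tolerance of 0.01 reads. The design fixed before the data were examined assumed raw counts with edgeR as the main test. Because the deposited unit is a normalized signal, the fallback named there, limma-trend on log2(value + 1), became the main test (2079 genes), and edgeR's quasi-likelihood test on the recovered reads, which called 2228 genes, an added alternative. A column header names only its cell line, so columns are assigned to a line and not to a particular sample, and the letters A and B follow column order. No column of per-sample values was left unused.

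The table has 15346 rows. Its 67 unnamed rows, holding 0.031% to 0.0369% of reads, were left out of library totals and tests, and 20 rows had gene names turned into dates and were not named. Genes were kept by edgeR's filterByExpr on the recovered reads (minimum count 10, minimum total 15), which left 14424 and removed 855. A log2 fold change is the brain metastatic mean minus the parental mean on the log2(value + 1) scale, which understates changes of low genes. P-values were adjusted by the Benjamini-Hochberg method over all tested genes with a threshold of 0.05, and values are means ± SD of 2 libraries. Composition values are given without a test, as planned. The replicate pairs are not copies of a library, since chi-square per degree of freedom was 62 over the genes of the parental pair and 124 over those of the brain metastatic pair. A read is worth 0.0325 to 0.0387 CPM (counts relative to the library total). A line without reads for a gene is given the limit of 3 reads over its libraries, and intervals for read ratios are exact binomial 95% intervals, which cover counting error only.

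Before the data were examined, 47 gene lists with 1567 entries were fixed, of which 1191 matched the table, 3 through older symbols; other entries were not analysed here. The lists cover matrix, proteases, integrins and cadherins, metastasis genes, NF-kappaB, chemokines, interferon, antigen presentation, MAPK and stress responses, epithelial, mesenchymal, stem-like, EGF, TGF-beta, Wnt, Notch, HOX and cancer-testis genes, axon guidance, neuronal and GABA or glutamate genes, cell cycle, p53, ribosomal protein and metabolic genes, including transporters, and markers of other cells and of RNA quality. Lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 43 lists. Of the remaining 4, the fibroblast, microglia and melanocytic markers are given as counts, and the mitochondrially encoded genes were not analysed here. The count of members passing is also given adjusted over the list alone. Camera with an estimated correlation, given beside the calls, has only 2 residual degrees of freedom, so hardly any list could pass it.

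Genes named in the text were set by a rule: the 10 largest increases and 10 largest decreases among genes with adjusted p below 0.05, a mean of at least 10 CPM in the higher line and no overlap between the lines' libraries, and in each list up to 2 passing members with the largest increase and up to 2 with the largest decrease at 5 or more CPM, or the most abundant member where none passed. XIST, Y-linked genes and repeated symbols were not eligible for the largest increases and decreases. The 3 most abundant genes of each line were added. The text may name fewer genes of a list. Alternatives comprised other tests (edgeR's quasi-likelihood and likelihood ratio tests, DESeq2 and limma-voom, all on recovered reads), other scalings, filters and pseudocounts, protein-coding genes alone, thinning to the smallest library, leaving out each library, and a loess correction of each library for transcript length and GC with a span of 0.5. Chromosome, transcript length and GC came from GENCODE v29, a release for GRCh38, by gene symbol (15227 of 15279 named rows matched), so no coordinates are given. Length and GC are those of each gene's longest transcript. The analyses used R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0 and Python 3.11.15. The tests were tried on simulated reads for the 14424 genes of this comparison with 200 genes changed: limma-trend recovered 11% of those changed by a log2 fold of 1 and 80% of those changed by a log2 fold of 2, with 2 false calls among 93, and edgeR 12% and 80%, with 3 false among 95. Camera called 0 of 40 unchanged simulated lists. Their genes were drawn independently, whereas members of real lists move together (estimated correlation up to 0.95, for ribosomal protein genes). The simulation therefore says nothing on false calls that such correlation can give, among lists or among single genes. Each simulated gene also had the same dispersion in both lines. In the data the median absolute log2 difference was 0.26 in the parental and 0.38 in the brain metastatic pair. The simulated share of false calls thus need not hold for the real calls.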

Results

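Gene expression was measured by RNA-seq in cultures of MDA-MB-231, a widely used triple-negative human breast cancer line, and of MDA-MB-231Br, its brain metastatic derivative. Each line was represented by 2 libraries, called here parental A and B and brain metastatic A and B in the column order of the deposited table. The reads assigned to named genes numbered 30771290 and 27554570 in parental libraries A and B, and 28107820 and 25835225 in brain metastatic libraries A and B. Genes with at least 1 read numbered 14970, 15028, 14938 and 15005 in the same order. The labels do not say that the libraries of a line came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Across the 14424 genes tested, log2 CPM (reads relative to the library total) of the parental pair correlated at r = 0.988 and those of the brain metastatic pair at r = 0.967, against 0.901 to 0.935 between lines. Genes are not independent replicates. The median absolute log2 difference was 0.26 between the parental libraries, 0.38 between the brain metastatic libraries and 0.47 between the means of the lines. The first principal component held 75.7% of the variance and separated the lines, and the second, with 18.4%, had brain metastatic libraries A and B at its ends.

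The comparison of breast cancer with brain metastatic cells, which the series design names, gave large changes in single genes. Higher in brain metastatic cells were CSMD1, a complement control protein with tumour suppressor activity, THBS2, a secreted matricellular thrombospondin, SPARC, a secreted collagen-binding glycoprotein, IL13RA2, a decoy receptor for interleukin 13, and AMOT, an angiomotin that binds YAP. Lower in brain metastatic cells were GSTP1, a glutathione transferase, PDGFRB, a platelet-derived growth factor receptor, the adhesion molecule gene MPZL2 and the adhesion G protein-coupled receptor gene ADGRF1. Of 14424 genes tested with limma-trend, 2079 (14.4%) changed at an adjusted p below 0.05, with 1242 higher and 837 lower in brain metastatic cells. Changes of at least 2-fold were fitted for 1841 of them.

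CSMD1 had no read in either parental library and a normalized count of 402 ± 70.0 (SD, n = 2) in brain metastatic cells (adjusted p = 0.00014), at least 293-fold higher when 3 reads over the parental group are taken as the limit that a count of 0 allows. TMEM47, a junctional tetraspan protein gene, likewise had no parental read and 275 ± 91.3 (SD, n = 2) in brain metastatic cells (adjusted p = 0.000201), at least 205-fold higher. THBS2 measured 8.2 ± 0.743 in parental and 3306 ± 179 in brain metastatic cells (SD, n = 2 each, log2 fold change 8.49 ± 0.294 SE, adjusted p = 2.56e-05), and SPARC 40.9 ± 10.8 in parental and 4397 ± 204 in brain metastatic cells (SD, n = 2 each, log2 fold change 6.74 ± 0.283 SE, adjusted p = 6.15e-05). IL13RA2 measured 16.5 ± 4.07 in parental and 1467 ± 40.5 in brain metastatic cells (SD, n = 2 each, log2 fold change 6.41 ± 0.318 SE, adjusted p = 9.20e-05). The remaining genes of the 10 with the largest increases were MUC15, a cell surface mucin (8.55), EPB41L3, a membrane skeleton protein (7.60), NAP1L2, a histone chaperone, AMOT (7.22) and PLCB1, a phospholipase C (6.90), all as log2 fold changes, with adjusted p between 8.62e-05 and 0.000153. NAP1L2 had only 3 parental reads, and its reads were 297 times higher in brain metastatic cells (95% counting interval 101 to 1445). MUC15 had 4 parental reads and a ratio of 555 (216 to 2039), and PLCB1 11 and a ratio of 143.7 (80.05 to 288.5). GSTP1 measured 4722 ± 629 in parental and 248 ± 13.7 in brain metastatic cells (SD, n = 2 each, log2 fold change -4.24 ± 0.236 SE, adjusted p = 0.00014), and PDGFRB 642 ± 158 in parental and 23.6 ± 11.6 in brain metastatic cells (SD, n = 2 each, log2 fold change -4.77 ± 0.418 SE, adjusted p = 0.000653). The other genes of the 10 with the largest decreases were MPZL2 (-6.92), the filamin regulator RFLNB (-6.22), MVB12B (-6.03), ADGRF1 (-5.26), SORCS2 (-5.10), SUSD3 (-4.58), LRRC61 (-4.30) and GPR176 (-4.20), with adjusted p between 0.00014 and 0.00427. Without parental library A the test called 421 genes and without parental library B 429, against 5257 without brain metastatic library A and 3147 without brain metastatic library B. Each of the genes of this paragraph passed in every one of those fits. MVB12B had a log2 fold change of -5.36 without brain metastatic library A and -6.69 without brain metastatic library B, and GPR176 -3.12 and -5.27. limma's treat, which tests for changes beyond 2-fold, called 314 genes, and edgeR's glmTreat on the recovered reads 523.

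**Figure D1:**
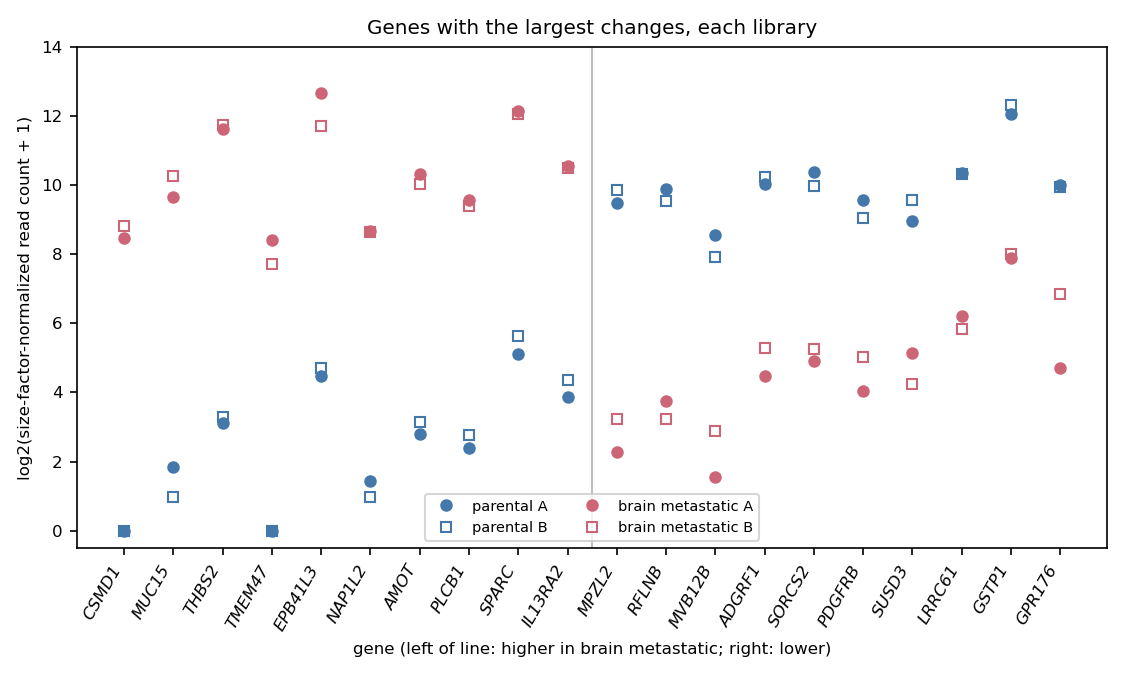
Each point is a library's log2 of the size-factor-normalized read count plus 1 for the 10 genes with the largest increases and the 10 with the largest decreases in brain metastatic cells (blue parental, red brain metastatic, filled circles library A, open squares library B). CSMD1 and TMEM47 are at 0 in both parental libraries.

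Matrix, protease and adhesion genes, such as THBS2, SERPINB2 and ITGB4, included more members higher than lower in brain metastatic cells with all libraries. The laminin and proteoglycan list had 11 of 27 tested members higher, 4 lower and 12 not passing (12 and 4 adjusted over the list alone). Given as log2 fold changes, THBS2 (8.49) was among those higher and EFEMP1 (-1.89) and LAMB1 (-1.74) among those lower (camera adjusted p = 0.0156, and adjusted p = 0.652 with an estimated correlation). The laminin call ended under the stricter expression filter (adjusted p = 0.075) and after correction for length and GC (adjusted p = 0.212, with its median at 0.92 before and 0.67 after). Matrix proteases and inhibitors had 11 of 35 tested members higher, 3 lower and 21 not passing (13 and 6 adjusted over the list alone). SERPINB2 (4.32), an inhibitor of plasminogen activators, and the metalloprotease gene ADAMTS1 (3.73) rose, and ADAM12 (-1.81) fell (camera adjusted p = 0.0146, and adjusted p = 0.652 with an estimated correlation). SERPINB2 had a log2 fold change of 3.46 without parental library A and 5.18 without parental library B. The protease call ended with camera on ranks (adjusted p = 0.0542). Integrins had 5 of 16 tested members higher, 1 lower and 10 not passing (5 and 1 adjusted over the list alone). ITGA10 (3.40) and ITGB4 (2.10), a laminin receptor subunit, rose and ITGB5 (-0.83) fell (camera adjusted p = 0.00649, and adjusted p = 0.652 with an estimated correlation). Cadherins had 6 of 16 tested members higher, 1 lower and 9 not passing (6 and 2 adjusted over the list alone). The largest increases were in FAT3 (3.98) and CDH18 (3.82), while CELSR2 (-2.44) fell (camera adjusted p = 0.021, and adjusted p = 0.652 with an estimated correlation). Collagens had 8 of 30 tested members higher, 2 lower and 20 not passing (9 and 2 adjusted over the list alone). COL1A1 (2.20) and COL4A5 (2.06) rose and COL18A1 (-1.52) fell. They were not called by camera (adjusted p = 0.119) with all libraries, but called higher without brain metastatic library A (adjusted p = 0.00431, and adjusted p = 0.712 with an estimated correlation and all libraries). Collagens had 7 higher and 7 lower without brain metastatic library B. The integrin, laminin, cadherin and collagen medians differed between the brain metastatic libraries, at 0.40 in library A and 0.99 in library B, 0.62 in library A and 0.90 in library B, 0.58 in library A and 1.62 in library B and 0.06 in library A and 0.76 in library B. The cadherin call ended without brain metastatic library B (adjusted p = 0.171), on ranks (0.076) and after correction for length and GC (0.116, with its median at 1.23 before and 0.83 after). Of the 124 distinct tested members, 52 passed with all 4 libraries. Without parental library A 19 passed, and without parental library B 21. Without brain metastatic library A 79 passed, and without brain metastatic library B 59. Genes of these lists not called in at least 1 of those fits included COL1A1, COL4A5, COL18A1, LOXL1, LAMB1, ADAM12, ADAMTS6, ITGB5 and CELSR2 (adjusted p up to 0.31).

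Genes that earlier studies tied to metastasis were more often higher than lower in brain metastatic cells. Those tied to brain metastasis or brain entry had 15 of 34 tested members higher, 1 lower and 18 not passing (17 and 1 adjusted over the list alone). The largest increases were in PLCB1 (6.90) and SERPINB2 (4.32), while S100A4 (-3.23), a calcium-binding protein gene tied to motility, fell (camera adjusted p = 2.02e-05, and adjusted p = 0.652 with an estimated correlation). S100A4 measured 10210.0 ± 3098 in parental and 1066 ± 167 in brain metastatic cells (SD, n = 2 each, log2 fold change -3.23 ± 0.274 SE, adjusted p = 0.000608). Those tied to lung or bone metastasis of this line had 13 of 26 tested members higher, 3 lower and 10 not passing (14 and 4 adjusted over the list alone). SPARC (6.74) and IL13RA2 (6.41) rose and the GTPase-activating protein gene DLC1 (-2.40) and the cytokine gene IL11 (-1.39) fell (camera adjusted p = 9.58e-05, and adjusted p = 0.652 with an estimated correlation). IL11 had a log2 fold change of -2.01 without brain metastatic library A and -0.77 without brain metastatic library B. SERPINB2 had a log2 fold change of 3.46 without parental library A and 5.18 without parental library B. Some of these genes came from comparisons of sublines of the same parental line, so the counts are not independent evidence of a direction. These lists had 27 distinct passing members with all 4 libraries, 15 without parental library A and 17 without parental library B. The number was 34 without brain metastatic library A and 36 without brain metastatic library B. Of the genes the naming rule gives for these lists, IL11 was not called in at least 1 of those fits (adjusted p up to 0.251).

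PTGS2, CXCL1 and EGR1 were higher in brain metastatic cells, and IL32 and IL11 were lower. NF-kappaB targets had 13 of 33 tested members higher, 0 lower and 20 not passing (16 and 0 adjusted over the list alone). Among these were PTGS2 (3.74), the inducible cyclooxygenase, and the survival gene BCL2A1 (3.61) (camera adjusted p = 2.65e-07, and adjusted p = 0.652 with an estimated correlation). Chemokines and interleukins had 9 of 25 tested members higher, 3 lower and 13 not passing (12 and 4 adjusted over the list alone). The neutrophil chemokine genes CXCL3 (3.55) and CXCL1 (3.50) rose, and IL32 (-2.31) and IL11 (-1.39) fell (camera adjusted p = 0.00433, and adjusted p = 0.652 with an estimated correlation). CXCL1 measured 916 ± 84.3 in parental and 10391 ± 1569 in brain metastatic cells (SD, n = 2 each, log2 fold change 3.50 ± 0.23 SE, adjusted p = 0.000194). The MAPK and AP-1 list had 11 of 30 tested members higher, 0 lower and 19 not passing (17 and 0 adjusted over the list alone). Among them were EPHA4 (4.18), an ephrin receptor, and the immediate early gene EGR1 (1.98) (camera adjusted p = 1.82e-06, and adjusted p = 0.652 with an estimated correlation). EGR1 is also in the list of dissociation and heat stress genes, a sign of handling, which had 6 of 21 tested members higher (camera adjusted p = 0.0218, and adjusted p = 0.652 with an estimated correlation). That list was not called without parental library B (adjusted p = 0.0549) or brain metastatic library A (adjusted p = 0.207). PTGS2 had a log2 fold change of 4.68 without brain metastatic library A and 2.80 without brain metastatic library B, BCL2A1 2.96 and 4.26, IL32 -1.72 and -2.90, and IL11 -2.01 and -0.77. NF-kappaB targets had a median log2 difference from the parental mean of 0.49 in library A and 1.40 in library B, whereas the MAPK and AP-1 median was 0.79 in library A and 0.69 in library B. Of the 80 distinct tested members, 31 passed with all 4 libraries. Without parental library A 11 passed, and without parental library B 16. Without brain metastatic library A 51 passed, and without brain metastatic library B 43. Of the genes the naming rule gives for these lists, IL32, IL11 and EGR1 were not called in at least 1 of those fits (adjusted p up to 0.251).

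OAS1 and OAS3 were higher in brain metastatic cells, and values of the interferon-stimulated list were higher mainly in brain metastatic library B. The list had 7 of 41 tested members higher, 0 lower and 34 not passing (10 and 0 adjusted over the list alone). Among these were the oligoadenylate synthetase genes OAS1 (5.17) and OAS3 (1.70). It was called higher (camera adjusted p = 2.02e-05, and adjusted p = 0.652 with an estimated correlation), a call that ended without library B (adjusted p = 0.394, 11 higher and 4 lower). OAS1 had a log2 fold change of 6.10 without brain metastatic library A and 4.24 without brain metastatic library B, and OAS3 2.47 and 0.93. The list's median log2 difference from the parental mean was 0.13 in library A and 1.86 in library B. IFIT2, chosen after its values were seen, had a normalized count of 357 in library A and 19260.0 in library B, against 666 and 709 in the parental libraries. Library B also had 0.171% of its reads in 15 mitochondrial pseudogenes, a possible sign of RNA quality. The share was 0.0483% in library A and 0.0431% and 0.0425% in parental libraries A and B. Antigen presentation genes had 6 of 18 tested members higher, 0 lower and 12 not passing (7 and 0 adjusted over the list alone). The largest increases were in HLA-DMA (2.56) and HLA-DMB (2.36), which load peptides onto class II molecules (camera adjusted p = 0.000903, and adjusted p = 0.652 with an estimated correlation). The HLA-DR, HLA-DP and HLA-DQ genes fixed for this list, and CD74, had no row in the deposited data. The class II molecules themselves were therefore not measured. The unfolded protein and integrated stress response list had 2 of 28 tested members higher, 0 lower and 26 not passing (1 and 0 adjusted over the list alone), the passing genes being CHAC1 (1.64), a glutathione-degrading enzyme gene, and CEBPB (0.80). It was called higher (camera adjusted p = 0.00569, and adjusted p = 0.652 with an estimated correlation), but not without library B (adjusted p = 0.539). Its medians were 0.18 in library A and 1.17 in library B. CEBPB lay close to the threshold (adjusted p = 0.0498) and did not pass with edgeR's quasi-likelihood test on the recovered reads (adjusted p = 0.0535). HSP90B1, an endoplasmic reticulum chaperone gene and among the 3 highest genes of the brain metastatic line, had log2 differences of 0.48 in library A and 2.15 in library B and did not pass (adjusted p = 0.101), although DESeq2 called it (adjusted p = 0.00237). These lists had 15 distinct passing members with all 4 libraries, 2 without parental library A and 3 without parental library B. The number was 63 without brain metastatic library A and 25 without brain metastatic library B. Of the genes the naming rule gives for these lists, OAS3, HLA-DMB, CHAC1 and CEBPB were not called in at least 1 of those fits (adjusted p up to 0.315).

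Epithelial and mesenchymal genes changed in both directions, with CLDN1 and VIM higher and KRT7 and S100A4 lower. Epithelial junction and keratin genes had 8 of 27 tested members higher, 2 lower and 17 not passing (10 and 4 adjusted over the list alone). The desmosomal cadherin gene DSC2 (2.37) and CLDN1 (2.19) rose and KRT7 (-2.64) and CLDN4 (-1.42) fell. Mesenchymal genes had 8 of 26 tested members higher, 6 lower and 12 not passing (9 and 9 adjusted over the list alone). SPARC (6.74) and WNT5A (1.87) rose and PDGFRB (-4.77) and S100A4 (-3.23) fell. Neither list was called (camera adjusted p = 0.154 and 0.855), except the epithelial list under the stricter expression filter (adjusted p = 0.0499, and adjusted p = 0.652 with an estimated correlation and the planned filter). VIM, the mesenchymal intermediate filament gene and among the 3 highest genes of the brain metastatic line, measured 40450.0 ± 2866 in parental and 118820.0 ± 1030.2 in brain metastatic cells (SD, n = 2 each, log2 fold change 1.56 ± 0.228 SE, adjusted p = 0.00473), without passing when parental library A or B was left out (adjusted p = 0.0769 and 0.101). Stem-like breast cancer markers had 2 of 13 tested members higher, 0 lower and 11 not passing (4 and 0 adjusted over the list alone), the passing genes being SOX4 (1.62) and ITGA6 (1.37). They were called higher (camera adjusted p = 0.021, and adjusted p = 0.652 with an estimated correlation). The call ended without parental library A (adjusted p = 0.0663) or brain metastatic library B (adjusted p = 0.0665), and the median was 0.56 in library A and 1.22 in library B. EGF family ligands and receptors had 1 of 15 tested members higher, 3 lower and 11 not passing (5 and 4 adjusted over the list alone). The ligand gene AREG (-2.98) and the receptor substrate gene EPS8 (-1.10) fell. The list was not called by camera (adjusted p = 0.856), and the sign of its median (0.02) changed under RLE and library-size scaling, without histone and mitochondrial pseudogene rows and after correction for length and GC (-0.14). EGF family genes had 5 higher and 4 lower without brain metastatic library A and 4 higher and 4 lower without library B. Mesenchymal genes had 9 higher and 9 lower without brain metastatic library A, 1 higher and 3 lower without parental library A and 2 higher and 3 lower without parental library B. AREG had a log2 fold change of -3.66 without parental library A and -2.31 without parental library B. Of the 80 distinct tested members, 30 passed with all 4 libraries. Without parental library A 9 passed, and without parental library B 11. Without brain metastatic library A 49 passed, and without brain metastatic library B 41. Of the genes the naming rule gives for these lists, CLDN4, WNT5A, EPS8, SOX4 and ITGA6 were not called in at least 1 of those fits (adjusted p up to 0.268).

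Developmental pathway genes such as WNT7B and LEF1 were higher and DKK1 and TGFBI lower, without a call for their lists. TGF-beta and BMP targets had 5 of 35 tested members higher, 3 lower and 27 not passing (5 and 6 adjusted over the list alone). JUNB (1.93) and the decoy receptor gene BAMBI (1.89) rose and TGFBI (-1.63) fell (camera adjusted p = 0.561). Wnt pathway genes had 6 of 24 tested members higher, 1 lower and 17 not passing (6 and 2 adjusted over the list alone). The ligand gene WNT7B (2.95) and LEF1 (2.15) rose and the secreted inhibitor gene DKK1 (-1.77) fell (camera adjusted p = 0.0959, 0.0389 under the stricter expression filter, and adjusted p = 0.652 with an estimated correlation and the planned filter). Notch pathway genes had 3 of 16 tested members higher, 3 lower and 10 not passing (3 and 4 adjusted over the list alone). DTX4 (4.71) and NOTCH4 (2.90) had the largest increases (camera adjusted p = 0.708). HOX genes had 3 of 8 tested members higher, 0 lower and 5 not passing (4 and 0 adjusted over the list alone), among them HOXB3 (1.46) (camera adjusted p = 0.182). Cancer-testis antigen genes had 2 of 7 tested members higher, 2 lower and 3 not passing (2 and 3 adjusted over the list alone). MAGED2 (1.35) rose and MAGED1 (-1.03) fell (camera adjusted p = 0.634). Both are MAGE family genes that are not restricted to testis and cancer. Notch genes had 4 higher and 7 lower and cancer-testis genes 2 higher and 4 lower without brain metastatic library B. BAMBI had a log2 fold change of 2.51 without brain metastatic library A and 1.28 without brain metastatic library B. These lists had 28 distinct passing members with all 4 libraries, 7 without parental library A and 7 without parental library B. The number was 43 without brain metastatic library A and 43 without brain metastatic library B. Of the genes the naming rule gives for these lists, BAMBI, IL11, LEF1, DKK1, MAGED2, MAGED1 and HOXB3 were not called in at least 1 of those fits (adjusted p up to 0.268).

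Some genes of the nervous system, such as ROBO1, NLGN1 and GAD1, were higher in brain metastatic cells, and NGFR was lower. Axon guidance genes had 12 of 37 tested members higher, 3 lower and 22 not passing (14 and 4 adjusted over the list alone). The largest increases were in EPHA4 (4.18) and the SLIT receptor gene ROBO1 (2.78), while SEMA3F (-1.99) fell (camera adjusted p = 0.021, and adjusted p = 0.652 with an estimated correlation). The call ended without brain metastatic library B (adjusted p = 0.234), on ranks (0.0578) and after correction for length and GC (0.174, with its median at 0.44 before and 0.36 after). The axon guidance median was 0.31 in library A and 0.75 in library B. ROBO1 measured 415 ± 47.2 in parental and 2952 ± 1076 in brain metastatic cells (SD, n = 2 each, log2 fold change 2.78 ± 0.299 SE, adjusted p = 0.00141). Neuronal and synaptic genes had 7 of 19 tested members higher, 2 lower and 10 not passing (9 and 4 adjusted over the list alone). The synaptic adhesion gene NLGN1 (2.94) and the scaffold gene SHANK2 (2.44) rose and the neurotrophin receptor gene NGFR (-3.58) fell (camera adjusted p = 0.154). GABA and glutamate signalling genes had 4 of 12 tested members higher, 1 lower and 7 not passing (6 and 2 adjusted over the list alone). The glutamate transporter gene SLC1A1 (1.84) and GAD1 (1.54), which makes GABA from glutamate, rose, and the kainate receptor gene GRIK4 (-2.95) fell (camera adjusted p = 0.484). The list had 4 higher and 4 lower without brain metastatic library B. NGFR had a log2 fold change of -2.24 without brain metastatic library A and -4.92 without brain metastatic library B. Of the 68 distinct tested members, 29 passed with all 4 libraries. Without parental library A 10 passed, and without parental library B 9. Without brain metastatic library A 42 passed, and without brain metastatic library B 35. Of the genes the naming rule gives for these lists, SEMA3F, NGFR, STMN3, SLC1A1 and GAD1 were not called in at least 1 of those fits (adjusted p up to 0.31).

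Some ribosomal protein, DNA replication and respiratory chain genes, such as RPL37, GINS2 and NDUFS6, were lower in brain metastatic cells, and CDKN1A was higher. Cytosolic ribosomal protein genes had 0 of 68 tested members higher, 17 lower and 51 not passing (0 and 38 adjusted over the list alone). Among these were RPL37 (-1.95) and RPS15 (-1.60) (camera adjusted p = 2.96e-13, and adjusted p = 0.652 with an estimated correlation). Their estimated correlation was 0.95, and their median log2 difference -0.58 in library A and -1.37 in library B. They took 3.44% and 5.25% of the reads in parental libraries A and B, and 2.84% and 1.7% in brain metastatic libraries A and B. Brain metastatic library B was also the one with most mitochondrial pseudogene reads (0.171%). G1-S and DNA replication genes had 0 of 50 tested members higher, 9 lower and 41 not passing (0 and 9 adjusted over the list alone). The helicase cofactor gene GINS2 (-1.63) and the histone chaperone gene CHAF1B (-1.36) fell (camera adjusted p = 4.02e-05, and adjusted p = 0.652 with an estimated correlation). Mitosis genes had 1 of 48 tested members higher, 1 lower and 46 not passing (0 and 0 adjusted over the list alone), the passing genes being KIF4A (0.95) and UBE2S (-1.32) (camera adjusted p = 0.021, and adjusted p = 0.652 with an estimated correlation). Mitosis genes had 1 higher and 12 lower without brain metastatic library A. The mitosis call ended without parental library A or brain metastatic library B (adjusted p = 0.153 and 0.278). Nuclear oxidative phosphorylation genes had 0 of 56 tested members higher, 5 lower and 51 not passing (0 and 2 adjusted over the list alone). The complex I genes NDUFS6 (-1.43) and NDUFA8 (-1.30) fell (camera adjusted p = 9.58e-05, and adjusted p = 0.652 with an estimated correlation). The list was not called without brain metastatic library B (adjusted p = 0.278), and its medians were -0.16 in library A and -0.84 in library B. p53 targets had 3 of 24 tested members higher, 1 lower and 20 not passing (3 and 2 adjusted over the list alone). The cell cycle inhibitor gene CDKN1A (1.70) and TP53I3 (1.61) rose (camera adjusted p = 0.513). CDKN1A measured 1361 ± 173 in parental and 4416 ± 411 in brain metastatic cells (SD, n = 2 each, log2 fold change 1.70 ± 0.228 SE, adjusted p = 0.00338). Ribosomal protein transcripts share reads with processed pseudogenes, so their single values are uncertain. These lists had 37 distinct passing members with all 4 libraries, 5 without parental library A and 1 without parental library B. The number was 138 without brain metastatic library A and 49 without brain metastatic library B. Of the genes the naming rule gives for these lists, GINS2, CHAF1B, KIF4A, UBE2S, NDUFS6, NDUFA8, TP53I3, RPL37 and RPS15 were not called in at least 1 of those fits (adjusted p up to 0.373).

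GSTP1 and MT1E fell and PHGDH rose, while most members of each metabolic list did not pass. Metallothioneins and NRF2 targets had 0 of 35 tested members higher, 10 lower and 25 not passing (0 and 12 adjusted over the list alone). The largest decreases were in GSTP1 (-4.24) and the metal-binding MT1E (-2.26), which has close paralogs (camera adjusted p = 0.000375, and adjusted p = 0.652 with an estimated correlation). Hypoxia response genes had 4 of 38 tested members higher, 1 lower and 33 not passing (4 and 1 adjusted over the list alone). The glycoprotein hormone gene STC1 (1.90) and hexokinase gene HK2 (1.29) rose and ALDOC (-1.31) fell. Glycolysis genes had 1 of 28 tested members higher, 3 lower and 24 not passing (1 and 3 adjusted over the list alone), and PDK4 (-2.28) fell. Cholesterol biosynthesis genes had 2 of 25 tested members higher, 3 lower and 20 not passing (2 and 8 adjusted over the list alone). NSDHL (0.91) rose and EBP (-1.46) and HMGCS1 (-1.03) fell. As a list they missed the threshold (camera adjusted p = 0.0546) and were called lower without parental library B (adjusted p = 0.0383) or brain metastatic library A (adjusted p = 0.0171). With all libraries they were also called lower without the low-count filter (adjusted p = 0.0461), among protein-coding genes alone (0.0368) and after correction for length and GC (0.0385). With an estimated correlation they were not called (adjusted p = 0.652), and on values corrected for length and GC no list was (smallest adjusted p = 0.707). Fatty acid genes had 2 of 29 tested members higher, 1 lower and 26 not passing (0 and 1 adjusted over the list alone). The desaturase gene SCD (-1.27) fell, and CPT1C (1.26) and ELOVL1 (0.84) rose. Amino acid metabolism genes had 5 of 30 tested members higher, 2 lower and 23 not passing (5 and 3 adjusted over the list alone). PHGDH (3.68), the first enzyme of serine synthesis, rose and BCAT1 (-1.06) fell. Their median (-0.11) and mean (0.09) differed in sign. PHGDH measured 55.9 ± 11.5 in parental and 749 ± 278 in brain metastatic cells (SD, n = 2 each, log2 fold change 3.68 ± 0.356 SE, adjusted p = 0.00083). Efflux transporters had 4 of 20 tested members higher, 1 lower and 15 not passing (5 and 1 adjusted over the list alone). ABCA5 (1.88) and ABCA3 (1.19) rose and ABCA2 (-1.19) fell. Hypoxia, glycolysis, fatty acid, amino acid and transporter lists were not called by camera (adjusted p = 0.0988, 0.538, 0.674, 0.66 and 0.348). Without parental library B the hypoxia list was called higher (adjusted p = 0.0224), and without brain metastatic library A the transporter list was (adjusted p = 0.0311). With an estimated correlation and all libraries these lists had adjusted p = 0.652 and 0.821. Transporters had 4 higher and 6 lower and fatty acid genes 3 higher and 3 lower without brain metastatic library B, and amino acid genes had 6 higher and 6 lower without library A. The transporter median was 0.06 in library A and 0.82 in library B. ABCA5 had a log2 fold change of 2.48 without brain metastatic library A and 1.28 without brain metastatic library B. Of the 190 distinct tested members, 37 passed with all 4 libraries. Without parental library A 4 passed, and without parental library B 4. Without brain metastatic library A 78 passed, and without brain metastatic library B 55. Genes of these lists not called in at least 1 of those fits included HK2, ALDOC, PDK4, NSDHL, EBP, HMGCS1, CPT1C, ELOVL1, SCD, CHAC1, BCAT1, SHMT1, ABCA5, ABCA3 and ABCA2 (adjusted p up to 0.351).

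Markers of other cell types changed in both directions, with KDR higher and CSF1R lower, and MALAT1 rose. Astrocyte markers had 2 of 6 tested members higher, 0 lower and 4 not passing (2 and 2 adjusted over the list alone), with CLU (1.16) higher, but 2 higher and 2 lower without brain metastatic library B. Endothelial markers had 3 of 7 tested members higher, 1 lower and 3 not passing (5 and 1 adjusted over the list alone). The VEGF receptor gene KDR (3.10) and ESAM (0.95) rose and EGFL7 (-3.50) fell. Luminal breast cancer markers had 3 of 14 tested members higher, 0 lower and 11 not passing (3 and 0 adjusted over the list alone). The transcription factor gene SPDEF (3.49) rose. These lists were not called by camera (adjusted p = 0.765, 0.0959 and 0.182). The endothelial list was called higher without parental library B (adjusted p = 0.0383) and the luminal list without brain metastatic library A (adjusted p = 0.00807). With an estimated correlation and all libraries both had adjusted p = 0.652. Fibroblast and pericyte markers had 1 of 3 tested members higher, 1 lower and 1 not passing (1 and 1 adjusted over the list alone), COL1A1 (2.20) and PDGFRB (-4.77). Microglia and leukocyte markers had 1 of 2 tested members higher, 1 lower and 0 not passing (1 and 1 adjusted over the list alone), LAPTM5 (1.24) and CSF1R (-2.76). Melanocytic markers had 0 of 3 tested members higher, 0 lower and 3 not passing (0 and 0 adjusted over the list alone), with RAB27A (0.46) the most abundant (adjusted p = 0.243). Replication-dependent histone genes had 4 of 10 tested members higher, 0 lower and 6 not passing (6 and 0 adjusted over the list alone), with HIST1H2AC (2.54) and HIST1H1C (2.23) the highest (camera adjusted p = 0.00225, and adjusted p = 0.652 with an estimated correlation). Dissociation and heat stress genes had 6 of 21 tested members higher, 0 lower and 15 not passing (9 and 1 adjusted over the list alone). Among these were EGR1 (1.98) and JUNB (1.93) (camera adjusted p = 0.0218, and adjusted p = 0.652 with an estimated correlation). The heat stress call ended without parental library B (adjusted p = 0.0549) or brain metastatic library A (adjusted p = 0.207), and under the stricter expression filter (0.0753). Nuclear noncoding RNA genes had 1 of 6 tested members higher, 0 lower and 5 not passing (1 and 0 adjusted over the list alone). They were called higher in the fit without brain metastatic library A (adjusted p = 0.0128, against 0.263 with all libraries, and adjusted p = 0.652 with an estimated correlation). MALAT1, a nuclear-retained RNA, rose (2.00, adjusted p = 0.0191). Its normalized counts were 6588 and 5207 in parental libraries A and B, 14306 in brain metastatic library A and 38186 in library B. EGFL7 had a log2 fold change of -4.21 without brain metastatic library A and -2.80 without brain metastatic library B, and MALAT1 2.71 and 1.29. The most abundant genes of the parental line, ACTB, HSP90AA1 and EEF1A1, had log2 differences of 0.09, -0.22 and -0.46 and did not pass (adjusted p = 0.841, 0.554 and 0.252). These lists had 24 distinct passing members with all 4 libraries, 10 without parental library A and 9 without parental library B. The number was 40 without brain metastatic library A and 32 without brain metastatic library B. Of the genes the naming rule gives for these lists, CLU, LAPTM5, CSF1R, ESAM, COL1A1, EGR1 and MALAT1 were not called in at least 1 of those fits (adjusted p up to 0.227).

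**Figure D2:**
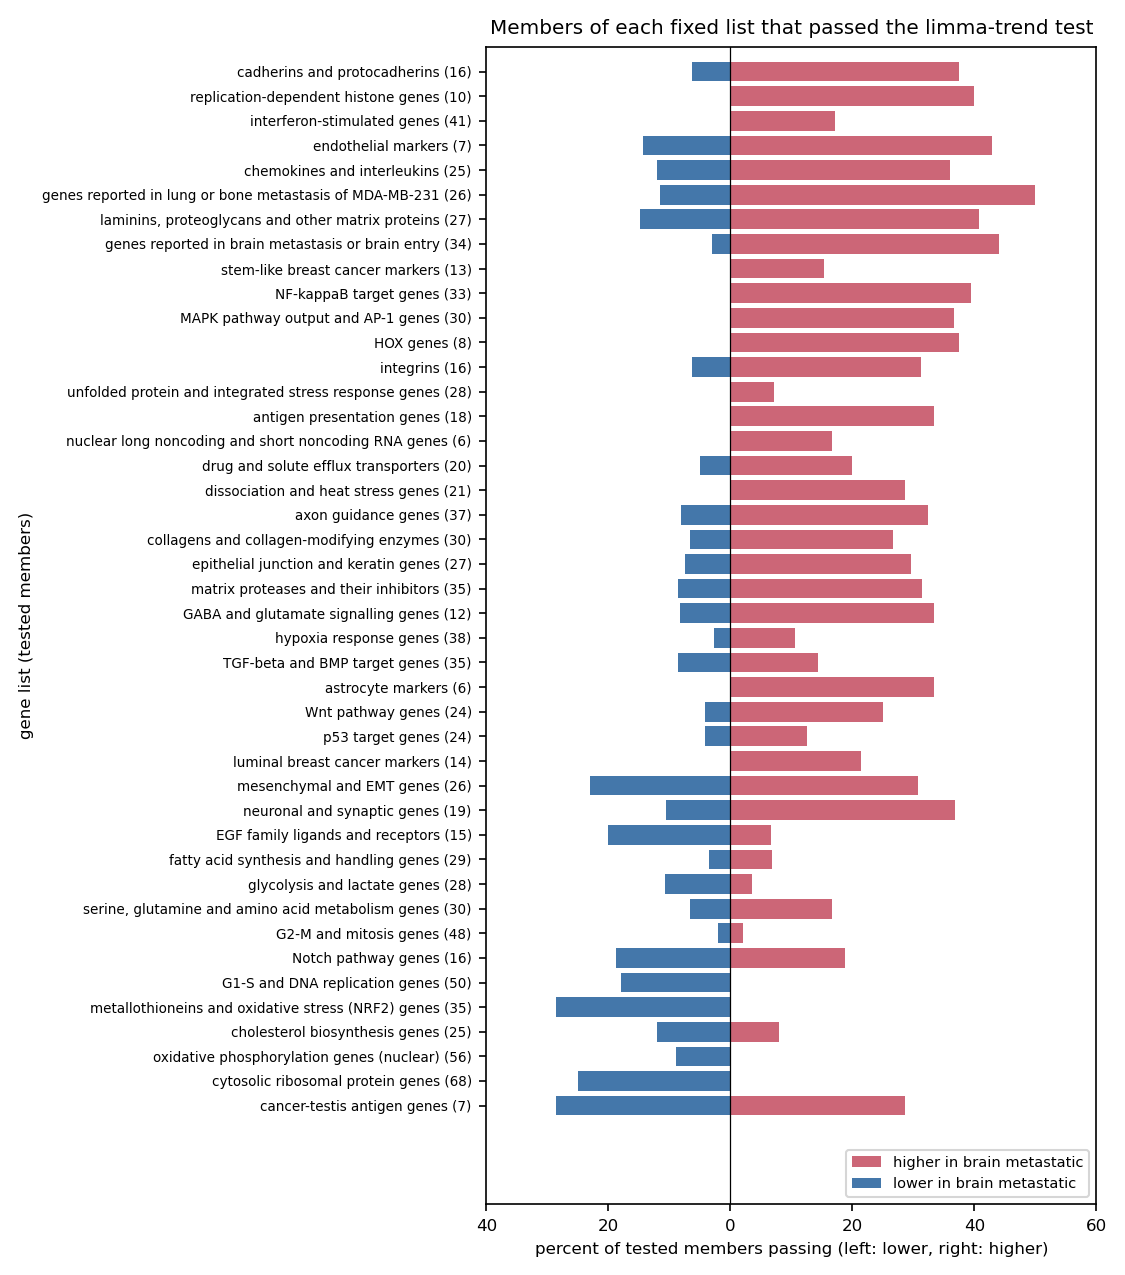
Bars give the percent of each fixed list's tested members (number in brackets) that passed the limma-trend test, to the right when higher and to the left when lower in brain metastatic cells; lists are ordered by their median log2 fold change. NF-kappaB targets had 13 of 33 members higher, and ribosomal protein genes 17 of 68 lower.

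Of the 43 lists with at least 5 tested members, camera with its preset correlation called 16 higher and 5 lower in brain metastatic cells. Those called lower were the ribosomal protein, G1-S, mitosis, oxidative phosphorylation and NRF2 lists. With an estimated correlation camera called 0 (smallest adjusted p = 0.652, and 1 list at an unadjusted p below 0.05). Fry, which asks whether a list's own genes move one way on balance, called 0 (smallest adjusted p = 0.0706, and 18 lists at an unadjusted p below 0.05). Fry's mixed test, which asks for changes in either direction, called 37.

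**Figure D3:**
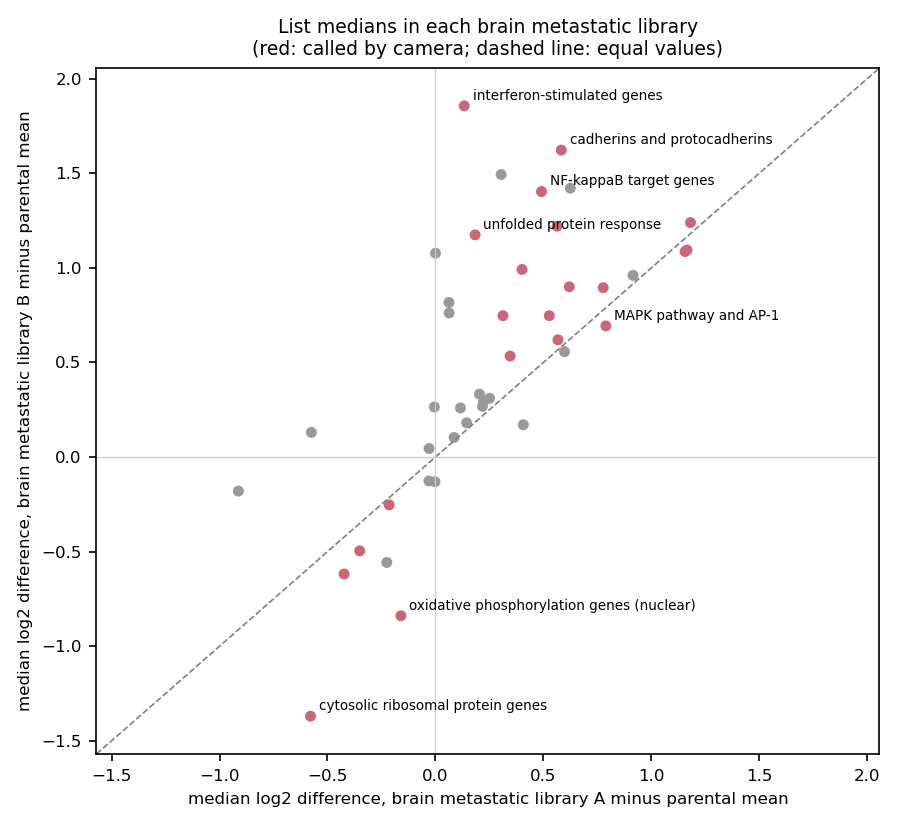
Each point is a fixed gene list, with the median log2 difference from the parental mean in brain metastatic library A (horizontal) and library B (vertical), red where camera called it with its preset correlation. Interferon-stimulated genes lie at 0.13 and 1.86, and ribosomal protein genes at -0.58 and -1.37.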

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

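The use of edgeR's quasi-likelihood test on recovered reads (planned for raw counts), the pseudocounts of 0.5 and 5, TMM scaling, limma's treat, the length and GC correction and camera with an estimated correlation on corrected values were chosen after the data were seen. The number of changed genes stayed within 1.5 times the 2079 of limma-trend under all settings that kept the 4 libraries except edgeR's likelihood ratio test (3196), between 1819 under the stricter filter and 3022 after the length and GC correction. Of the 2079 genes, 2051 were also called by edgeR's quasi-likelihood test, 2036 by DESeq2 and 2029 by limma-voom, and no gene of them changed sign under any setting that tested it. Genes lower in brain metastatic cells, 837 by limma-trend, numbered 1287 with DESeq2, 1437 with edgeR's likelihood ratio test and 1362 after the length and GC correction. The cause was not tested. Genes changed at least 2-fold, 1841 by limma-trend with a size filter, numbered 314 with limma's treat and 523 with edgeR's glmTreat, which test against that bound. Leaving out a library gave 421 to 5257 changed genes, 310 to 2855 higher, 74 to 2402 lower and 421 to 3717 changed at least 2-fold, the low values without a parental and the high ones without a brain metastatic library. In these fits a line has a lone library, assumed to vary like the other line's pair. With the parental libraries intact the spread is that of the closer pair, which gives more calls. Higher genes made up 59.7% of calls with all libraries, but 73.6% and 82.8% without parental library A or B, and 54.3% and 53.1% without brain metastatic library A or B. Gene lists called, 21 with camera's preset correlation, fell to 0 with an estimated correlation, 0 on corrected values with an estimated correlation and 0 with fry, and numbered 14 to 25 over the fits that left out a library and 18 to 22 over the others. With an estimated correlation camera has only 2 residual degrees of freedom, so hardly any list could pass it. Its fall to 0 therefore decides nothing about single lists. The cause of the other losses was not tested. The filters, length and GC correction and rank test ended calls for the laminin, protease, cadherin, axon guidance and heat stress lists (adjusted p = 0.0542 to 0.212), and leaving out the histone genes left their list untested. The stricter filter kept 18 of the 21 calls and also left a called list untested. Of the 122 called genes that the rule names, 114 kept their call under every setting with all libraries that tested them. Many of the 122 lost it when a parental library was left out, and few when a brain metastatic library was. Leaving out a library moved the fold of 16 of these 122 genes by more than 1.5 times. IFIT2, not called with all libraries, passed as lower without brain metastatic library B (log2 fold change -0.94) and as higher without brain metastatic library A (4.81), so the line's direction for it rests on which library is kept. Thinning to the smallest library called 2052 genes, 1994 of them among the 2079. Camera was not run with DESeq2, limma-voom or edgeR's likelihood ratio test, so these have no list counts. Replicate correlations were 0.9811 to 0.9884 for the parental pair and 0.954 to 0.9687 for the brain metastatic pair over the filters and prior counts tried. No paired analysis was possible because the table's columns carry no replicate number. The 11% recovery of simulated 2-fold changes does not carry over to these data. Only 200 genes were changed there, against 2079 called here, which makes the adjusted threshold stricter in the simulation. In the data 2902 genes had a line-mean difference above a log2 of 1, and 1841 calls were of at least 2-fold. With 2 libraries per line, changes may still be missed, and their share is unknown.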

Other observations

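Changed genes were unevenly spread over the chromosomes, which was noticed in the data and not planned. Every test in this part was chosen after its pattern had been seen, including the chromosome counts, whereas the bounds that decide each explanation were written before the result measured against them. On the X chromosome 153 of 542 tested genes were higher in brain metastatic cells (28.2%, against 7.85% elsewhere, Fisher's exact test adjusted p = 1.04e-40) and 73 were lower (13.5%, against 5.52%, adjusted p = 3.25e-10). TMEM47, NAP1L2, AMOT and IL13RA2 lie on it. Chromosomes 18, 4, 8 and 6 also held more higher genes (20.8%, 14.8%, 12.8% and 11%), and chromosomes 21, 9, 7 and 5 more lower genes (15.1%, 12.4%, 11.9% and 9.53%), all at adjusted p of 0.0371 or less over 46 tests, which treat genes as independent. The median log2 difference from the parental mean was 0.39 and 0.37 for X in brain metastatic libraries A and B, 0.31 and 0.32 for chromosome 18, -0.34 and -0.26 for chromosome 7 and -0.30 and -0.30 for chromosome 9, against a median of 0.01 over all of these genes.

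After each library was corrected for transcript length and GC, the odds ratio of higher calls on X against elsewhere was 4.85 (95% interval 4.01 to 5.84, and 4.62 before), which argues against that trend as the whole cause of the higher genes. For lower calls it went from 2.66 to 1.86 (1.45 to 2.37), which lies between the bounds written for this explanation. An excess remained after correction, so the trend stays open as a cause of part of it only. Lower calls over all genes numbered 837 before and 1362 after correction, so the odds ratios do not compare the same calls. Log2 fold changes of X-linked genes 10 tested genes apart had a Spearman correlation of 0.384, outside the -0.0922 to 0.0796 that held 95% of 1000 shuffles of gene order, as regional differences along the chromosome would give. The same correlation passed on 12 of 23 chromosomes, among them chromosome 19 (0.339), where clusters of related genes lie together. Shared regulation of neighbours therefore stays open. The values were not corrected for length and GC, so such a trend shared by neighbours stays open too. The correlation did not pass on chromosomes 4 (0.0364, adjusted p = 0.273) or 21 (-0.067, adjusted p = 0.77). Shuffling gene order within a chromosome cannot show a shift of the whole chromosome, so these misses decide nothing on such a shift. The median log2 fold change was 0.29 on chromosome 4 and -0.38 on chromosome 21. A candidate explanation for part of the X pattern is that the lines differ in copy number over stretches of it, but DNA was not analysed here. The largest differences of single X-linked genes need not share that cause. IL13RA2, for example, had 36 parental and 2914 brain metastatic reads, and changes in regulation were not tested.

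Interferon-stimulated genes separated the brain metastatic libraries: 37 of 41 tested members were higher in library B than in library A, with a median difference of 1.64, and library A exceeded the parental mean in 24 members and library B in 40. The median stayed at 1.54 (bootstrap 95% interval over members 1.07 to 2.14) after correction for length and GC, which argues against that trend as the whole cause. The interval treats members as independent, although their estimated correlation was 0.59, and does not cover the spread between libraries. Thinning to equal depth left it at 1.64 (0.921 to 2.24), but library A had only 1.09 times the reads of library B, so thinning could not have moved it much and decides nothing. A difference between cultures, such as an interferon response active in only 1 of them, may be the source and was not tested. A difference in handling or RNA quality stays open too, since library B had 0.171% of its reads in mitochondrial pseudogenes against 0.0425% to 0.0483% in the others.

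Ribosomal protein genes were below the parental mean in both brain metastatic libraries for 63 of 68 members, and shorter transcripts as a whole were lower in library B, whose median difference from library A ran from -0.42 in the shortest of 5 length groups of protein-coding genes to 0.31 in the longest, while the parental libraries ran from 0.26 to -0.16. After correction for length and GC the median log2 fold change of ribosomal protein genes was -0.766 (bootstrap 95% interval over members -0.943 to -0.645, and -0.976 before). The fitted trend thus removed part of the difference. Length was that of each gene's longest transcript, with a median of 1864.5 bases for these genes. The transcripts expressed may be shorter, so the correction cannot bound the share due to a bias against short transcripts. A shift of reads to pseudogenes is argued against, since 140 tested ribosomal protein pseudogenes had a median of -0.966 (-1.06 to -0.843), as low as their parent genes. These intervals treat members as independent, although the ribosomal protein genes had an estimated correlation of 0.95. They do not cover the spread between libraries. Against the parental mean, library A had a median of 0.005 in the shortest and 0.03 in the longest length group, and library B -0.38 and 0.36. The ribosomal protein median was -0.58 in library A and -1.37 in library B. These length groups thus show no trend behind the decrease in library A. For the ribosomal protein genes the median of library B minus A was 0.65 in the parental and -0.76 in the brain metastatic pair. The share of reads also differed within the parental pair (3.44% and 5.25%), and a library difference in the recovery of short transcripts or a slower growth of the brain metastatic cells may each contribute and stay open.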
